A study of Arabidopsis thaliana with 4 samples.

How the data were processed

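Transcript levels were measured on 4 Affymetrix ATH1 arrays of Arabidopsis thaliana inflorescence tips, 2 from the mutant tmm-1 and 2 from Col-3 gl1, the control. Per the labels, plants were grown in chambers on a peat-based soil at 22 °C, 70% humidity and 16 h of light at 125 µmol per square metre and second, and were taken at growth stage 6.10. Total RNA was purified on Qiagen columns and labelled with biotin in the one-cycle protocol, per the labels' protocols. Each array held a pool of tissue. The labels give every array the same replicate number, so the pool number in them was used as the replicate number here. The labels do not say whether the pools came from separate sets of plants. Thus p-values reflect at most the spread between pools, which may be technical. Nor do the labels say whether the mutant line also carries gl1.

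The intensity values deposited by the authors are MAS5 signals on a linear scale, and the submitters' processing notes name MAS5 and GCOS. MAS5 subtracts a background and combines the probe pairs of a probe set into a single signal. The 2% trimmed mean of each array was 100 in the deposited values, so the arrays were on a common scale and were not scaled again. A global scaling of this kind removes any overall difference in RNA content between groups. Detection calls were not used here. As a yardstick for background, the highest signal of any of the 27 Bacillus control probe sets on any array was 21.2. No other per-sample column was used.

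The table held 22810 probe sets, of which 64 were array controls. A pseudocount of 10 was added and values were put on the log2 scale, so fold changes on this scale understate the change of dim probe sets. Probe sets with a mean signal over the 4 arrays of at least 10 were tested, which left 16960. Differences between tmm-1 and Col-3 gl1 were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend on mean intensity), two-sided, with Benjamini-Hochberg adjustment. A probe set was called at an adjusted p below 0.05. Standard errors (SE) are the moderated ones of that model. They and the p-values rest mostly on the variance trend over all probe sets, with 23.6 prior degrees of freedom. The spread of each probe set's own pools counts for less. Standard deviations (SD) are of the signals of 2 arrays. An exact permutation test of 2 arrays against 2 cannot go below a two-sided p of 0.33, so single genes were judged by limma alone. The number of arrays limits the precision.

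The model was tested on simulated data for this comparison, with 200 of 16960 probe sets changed by a log2 of 1 or 2. It recovered 58% of the changes of 1 and 92% of those of 2, and 3 of its 153 calls were false. The simulated variances were drawn from the fitted model itself, with independent noise. The simulation thus cannot show whether the variance trend suits these arrays.

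Gene names came from a platform annotation of the array joined through Entrez gene IDs to the RefSeq genes of assembly TAIR10.1. That annotation gave 13513 probe sets with a single gene symbol and 503 with several. It did not list the other 8794, which are unnamed here. Of those with a single symbol, 13436 matched a RefSeq locus. No listed probe set stood for TMM or GL1, so the levels of both genes, and with them a check of the line labels, are not analysed here. Where several probe sets stood for a locus, that with the highest mean signal was used.

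Before the data were examined, 17 gene lists with 274 members were fixed. Of these members 37 had a named probe set and 23 passed the signal filter. Lists with at least 3 such members were tested with limma's camera at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry. Genes were named by a rule fixed at the same time. It took TMM, GL1 and the members of the stomatal lineage and guard cell lists that passed the filter, at most 8 per list in full. It also took the 10 largest rises and 10 largest falls among called probe sets with a single locus whose tmm-1 signals both lay above, or both below, the 2 control signals. From each other list it took called members, at most 4, or, where none was called, the 2 with the smallest p. TRY, RCA and COR47 complete their lists, and they and the further called genes given by name were chosen after their values were seen. Called loci were compared between chromosomes with Fisher's exact test, and in a 5 Mb window centred on TMM with a one-sided permutation test of 100000 resamples.

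Alternatives were another pseudocount, quantile normalization, scaling to the median, other signal filters, other variance models, other thresholds, the pool number as a block, and each array left out in turn. The pool number was not used as a block in the main model, since the labels do not say that it marks a shared day or batch. To look at an array that took no part in choosing genes, genes called without it were compared with its own signals, with a 95% bootstrap interval from 10000 draws. A filter at the highest Bacillus control signal was added after the data were seen.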

Results

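The series set tmm-1, a mutant of the stomatal patterning gene TMM, against Col-3 gl1, a line whose gl1 mutation removes most leaf hairs. The series title names its subject as the fate of meristemoids, the stem-cell-like precursors of stomata. TMM encodes a leucine-rich repeat receptor-like protein. Inflorescence tips were measured on 2 arrays per line. Median signals were 41.4 and 45.5 array units on tmm-1 replicates 1 and 2, and 40.8 and 40.7 on the control arrays. The dim end of tmm-1 replicate 2 lay higher than elsewhere, with a 10th percentile signal of 3.06 against 1.54 to 1.60 on the other 3 arrays. Its correlations with the other arrays, across probe sets, were 0.958 to 0.966, against 0.974 to 0.979 among those 3. The median absolute difference between replicates was 0.223 on the log2 scale for tmm-1 and 0.186 for the control. Ratios of 3' to 5' signal of the actin control were 2.29 and 2.47 in tmm-1 and 2.25 and 2.39 in the control, so the lines overlapped in this sign of RNA quality. The 25S ribosomal RNA control gave 957 and 2542 in tmm-1 and 1743 and 3025 in the control.

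Transcripts lower in tmm-1 included AT2G15960, which fell from 724 ± 162 (SD, n = 2) in the control to 206 ± 4.26, a 3.51-fold difference in mean signal (log2 change -1.75 ± 0.16, SE, adjusted p = 2.0e-07). COR27 (AT5G42900), a cold-regulated gene tied to the circadian clock, fell from 66.9 ± 3.57 to 9.34 ± 9.41, a log2 change of -2.08 ± 0.31 (adjusted p = 3.8e-04). Both tmm-1 values of COR27 were at or under the highest Bacillus control signal of 21.2, so the size of its change followed the pseudocount, at -3.10 with 1 and -1.60 with 20, and it was -1.56 without tmm-1 replicate 2. AT3G10020 fell from 751 ± 58.2 to 292 ± 37.6 and AT2G32150, which encodes a hydrolase of the haloacid dehalogenase family, from 371 ± 62.9 to 152 ± 3.28. AKINBETA1 (AT5G21170), a regulatory subunit of the SnRK1 energy-sensing kinase, fell from 487 ± 33.9 to 237 ± 14.7, a log2 change of -1.01 ± 0.15 (adjusted p = 3.2e-04).

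Taken at the brightest probe set of each locus, the 10 largest falls also held AT2G05540, a glycine-rich protein gene with a log2 change of -1.16. AT3G49080 was left out of them, since its called probe set, at -1.26, was not its brightest, which was at -0.15 and not called. AT5G61590, which encodes an AP2/ERF transcription factor known as DEWAX that represses wax genes, changed by -1.07 ± 0.16, from 311 ± 1.25 to 144 ± 27.3. AT2G16660, of the major facilitator family, changed by -1.01. AT1G75180 was 2.12-fold lower in mean signal. AT1G56220, of the dormancy- and auxin-associated family, was the brightest of these 10, at 1513 ± 222 in the control and 754 ± 142 in tmm-1. Further called genes with lower signal included MCCA (AT1G03090), a subunit of methylcrotonyl-CoA carboxylase in leucine breakdown, at -0.99 ± 0.16. ATL8 (AT1G76410), a RING-type ubiquitin ligase gene, was at -0.80 ± 0.17 and PORB (AT4G27440), a protochlorophyllide oxidoreductase of chlorophyll synthesis, at -0.65 ± 0.15. CCL (AT3G26740) had the smallest called fall, -0.62 ± 0.14, with 1501 ± 99.4 in the control and 972 ± 0.938 in tmm-1.

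Among transcripts higher in tmm-1, AT5G03350, which encodes a legume lectin family protein, was the brightest named gene, at 919 ± 43.6 against 448 ± 8 in the control (log2 change 1.02 ± 0.14, adjusted p = 1.1e-04). A further lectin gene of that family, AT3G16530, rose 3.57-fold in mean signal, from 41.7 ± 2.62 to 149 ± 7.43 (log2 change 1.62 ± 0.18, adjusted p = 4.7e-06). AT4G01870 rose from 30.9 ± 3.41 to 97.6 ± 20.6 and AT3G22240 from 18.2 ± 6.78 to 64.4 ± 0.708. CHI (AT2G43570), of the chitinase family, rose from 22.6 ± 5.88 to 62.0 ± 18.4, a log2 change of 1.13 ± 0.25. PPDK (AT4G15530), which makes phosphoenolpyruvate from pyruvate, rose from 19.9 ± 6.55 to 55.3 ± 9.41, and JRG21 (AT3G55970), a jasmonate-regulated oxygenase gene, from 12.3 ± 3.46 to 45.9 ± 14. AT3G60420, AT2G18690 and AT3G26960 had log2 rises of 1.95, 1.66 and 1.56. In these 3 genes and in JRG21, both control signals were at or under 21.2, so no fold of raw signal is given and the log2 rises depended on the pseudocount. With a pseudocount of 1 the rises of AT3G60420, AT2G18690 and AT3G26960 were 3.56, 2.61 and 2.33, with AT3G60420 no longer called (adjusted p = 0.054), and with 20 they were 1.38, 1.22 and 1.18. Further called genes with higher signal were AT4G29270, an acid phosphatase family gene, at 0.96 ± 0.20, AT1G10640, a pectin lyase-like gene, at 0.92 ± 0.19, AT2G36200, a kinesin gene, at 0.89 ± 0.19, and AT1G69730, of the wall-associated kinase family, at 0.78 ± 0.17.

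**Figure D1:**
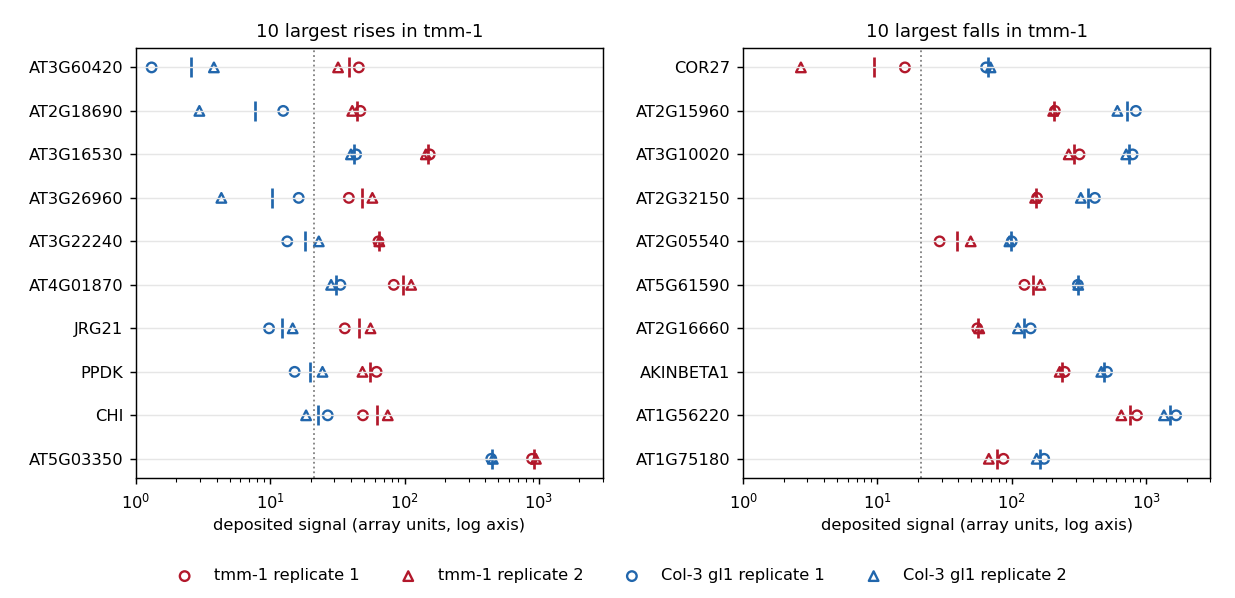
Deposited signal in array units (log axis) of the 10 named genes with the largest log2 rises and the 10 with the largest falls in tmm-1. Each locus is taken at its brightest probe set, which leaves out AT3G49080, called at a dimmer probe set with a log2 change of -1.26. Circles and triangles are replicates 1 and 2, and short vertical bars are the means of 2 arrays. Red is tmm-1, blue is Col-3 gl1, and the dotted line is the highest Bacillus control signal, 21.2. For each gene the signals of the 2 genotypes do not overlap, as the naming rule required.

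Over all 16960 probe sets tested, limma called 104, with 41 higher and 63 lower in tmm-1. Of these, 41 stood for a single locus, 14 higher and 27 lower, 6 stood for several genes and 57 were unnamed. Among unnamed probe sets, 267461_at fell from 3006 ± 116 to 531 ± 14.3 and 253161_at from signals of 499 and 588 to 162 and 191. Probe sets 245035_at and 256766_at rose from 83.6 ± 15.1 to 411 ± 15.7 and from 30.9 ± 2.58 to 156 ± 10.1. The called rises spanned log2 values of 0.71 to 2.62 with a median of 1.31, and the called falls spanned -2.48 to -0.62 with a median of -0.94. Median control signals were 29.9 for the probe sets called higher and 311 for those called lower, and median tmm-1 signals were 88.6 and 151. Both control arrays were at or under 21.2 for 12 of the 41. In all 104 the 2 tmm-1 signals lay on the same side of both control signals, as in 38.3% of all tested probe sets, where chance gives 33.3%. The count depended on the intensity trend and on the signal filter. Limma without the intensity trend called 0, with 1293 probe sets at an unadjusted p below 0.05 against 1495 with the trend. A filter of 3 times the minimum signal left AT3G60420, AT2G18690, AT3G26960 and JRG21 untested, as too dim. The count was 17 without the signal filter, which kept 6 of the 20 named genes. It was 69 after quantile normalization, 662 without tmm-1 replicate 1 and 167 without tmm-1 replicate 2. Of the 20 named genes, AT3G60420, JRG21, PPDK and AT2G16660 were not called without control replicate 1, AT2G18690, AT3G26960 and CHI without control replicate 2, JRG21 and CHI without tmm-1 replicate 2, PPDK with a filter of 3 times the minimum signal (adjusted p = 0.0536), and AT2G18690, AT3G26960, JRG21, PPDK and CHI after quantile normalization.

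**Figure D2:**
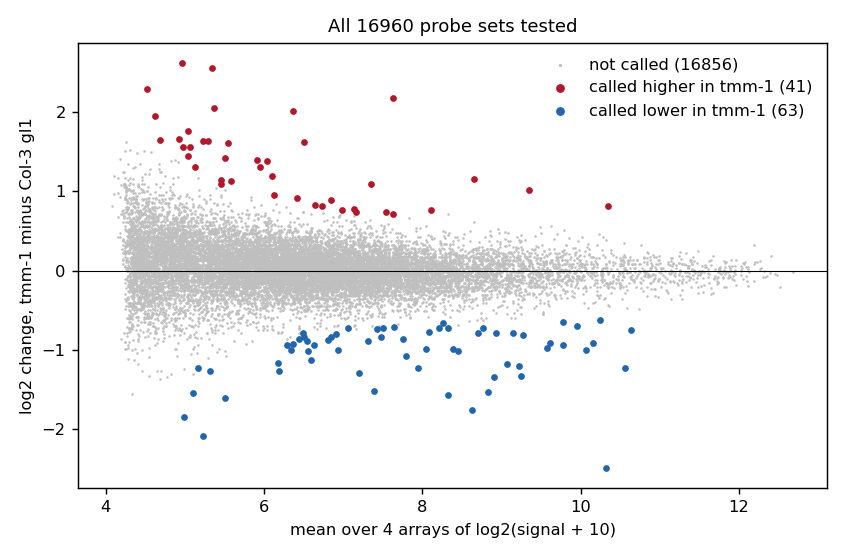
Log2 change in tmm-1 relative to Col-3 gl1 against the mean over 4 arrays of log2(signal + 10), with a point for each of the 16960 probe sets tested. The 41 called higher (red) lie mostly toward the dim side, and the 63 called lower (blue) extend to bright probe sets.

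The stomatal lineage genes that could be tested were not called in either direction. The mutated gene's known role makes this lineage the first group of interest. Of 19 listed members, 6 had a named probe set and 5 passed the filter. SPCH (AT5G53210), the transcription factor that starts the lineage, had signals of 76.1 and 46.2 in tmm-1 and 46.1 and 45.6 in the control, a log2 change of 0.32 ± 0.22 (adjusted p = 0.749), which was 0.01 without tmm-1 replicate 1 and 0.62 without tmm-1 replicate 2. FAMA (AT3G24140), which acts at the last step of guard cell formation, had 56.9 ± 9.80 in tmm-1 and 66.9 ± 4.20 in the control (-0.21 ± 0.20). TCX3, AGL16 and BRXL2 were at 0.19 ± 0.18, 0.16 ± 0.24 and 0.10 ± 0.26, the last of these with a reversed sign, -0.01, without control replicate 1. AGL16 stood at -0.04 without control replicate 2. MUTE was under the filter, with signals of 1.41 and 5.40 in tmm-1 and 0.867 and 1.18 in the control. As a group the 5 had a median log2 change of 0.16 (camera, adjusted p = 0.471, or 0.539 as an adjusted p with an estimated correlation). That median was 0.07 without tmm-1 replicate 2, 0.01 without control replicate 1 and 0.08 after quantile normalization.

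Genes of the related epidermal lists that could be tested were not called either. These were 1 of 12 listed stomatal receptors and kinases, 1 of 21 guard cell genes, 1 of 16 epidermis and cuticle genes and 3 of 13 trichome genes. The other listed genes had no named probe set or were under the filter, and some could be among the 57 unnamed called probe sets. EPFL9 (AT4G12970), a secreted peptide that promotes stomata, had 84.3 ± 22.9 in tmm-1 and 108 ± 4.48 in the control, a log2 change of -0.35 ± 0.19 (adjusted p = 0.637), which was -0.60 without tmm-1 replicate 1 (adjusted p = 0.0927) and -0.10 without tmm-1 replicate 2. The guard cell ion exchanger CHX20 was at 12.7 ± 0.772 and 18.2 ± 8.08, and its sign turned without control replicate 1, to 0.02. GASA9 and BLUS1 were under the filter. The receptor kinase gene ACR4 of the epidermis list was at -0.15 ± 0.40. Among 3 trichome genes, GIS was at 0.53 ± 0.21 (adjusted p = 0.422), SIM at 0.16 ± 0.17 and TRY at -0.20 ± 0.39, and the list's median was 0.16 (camera, adjusted p = 0.304), or 0.42 without tmm-1 replicate 2. ACR4 and TRY stood at 0.38 and 0.42 without tmm-1 replicate 2, the array with the raised dim end, and TRY at 0.15 without control replicate 2.

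Over all 17 lists, limma tested 23 members and called 0 over all probe sets, 4 had an unadjusted p below 0.05, and 3 passed when adjusted over the list alone, namely COR15A, GI and AUR1. COR15A (AT2G42540), a cold-induced chloroplast protein gene, had 94.0 ± 24.8 in tmm-1 and 49.0 ± 8.69 in the control, a log2 change of 0.80 ± 0.21 (adjusted p = 0.0796 over all probe sets and 0.00196 adjusted over the list alone). Its log2 change was 1.05 without tmm-1 replicate 2, 0.95 without control replicate 2, 0.56 without tmm-1 replicate 1 and 0.65 without control replicate 1. Limma called it over all probe sets with the pool number as a replicate block (adjusted p = 0.0393). The other members of the abscisic acid and cold list, LTI30 and COR47, were at 0.14 ± 0.18 and 0.11 ± 0.15. That list's median was 0.14 (camera, adjusted p = 0.0974, or 0.467 as an adjusted p with an estimated correlation), and its adjusted p was 0.00421 without tmm-1 replicate 2 and 0.0429 without control replicate 2, where the adjusted p with an estimated correlation was 0.596 and 0.569. GI (AT1G22770), a clock and flowering gene, had 105 ± 6.86 in tmm-1 and 149 ± 2.91 in the control (-0.47 ± 0.17, adjusted p = 0.325), and AUR1 (AT4G32830), a mitotic kinase gene, had 261 ± 3.14 and 201 ± 0.335 (0.36 ± 0.15, adjusted p = 0.478). GI and AUR1 were each the 1 tested member of their list, where adjustment over the list changes nothing.

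Photosynthesis genes LHCB4.1, PRK and RCA were at -0.28 ± 0.14, -0.11 ± 0.14 and -0.10 ± 0.16, with a median of -0.11 (camera, adjusted p = 0.176). Without control replicate 2 that median was -0.35 (adjusted p = 0.0351, or 0.569 as an adjusted p with an estimated correlation). GH3.5 and ARR15 of the auxin and cytokinin list were at -0.36 ± 0.26 and -0.01 ± 0.18, the stress regulator ZAT10 at 0.16 ± 0.19, and the anther receptor kinase gene EMS1 at -0.05 ± 0.37. The named members of the meristem and floral identity, late pollen and heat shock lists were all under the filter. Members of the vascular and secondary wall and salicylate defence lists are not analysed here.

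**Figure D3:**
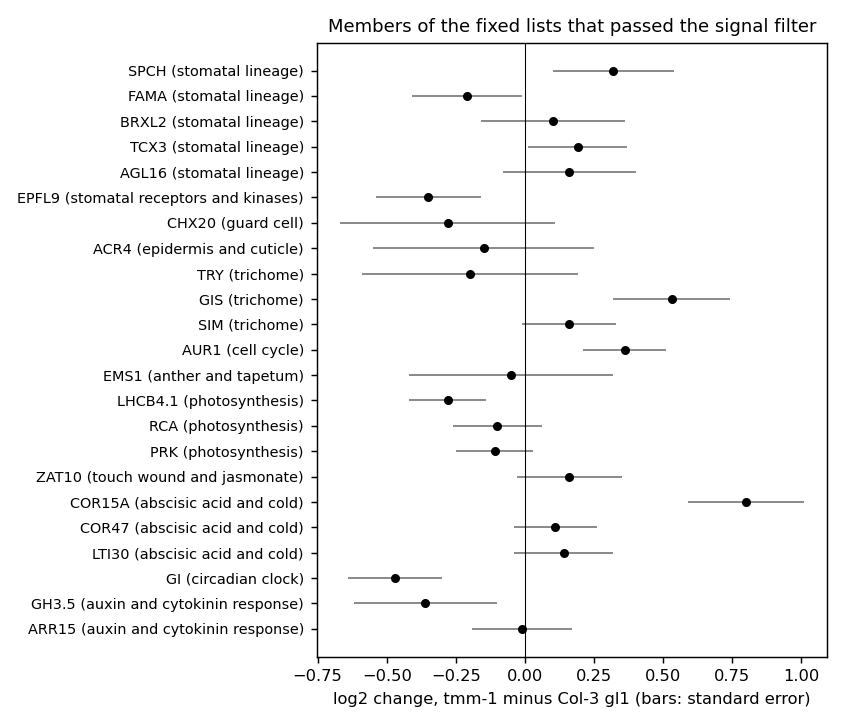
Log2 change in tmm-1 relative to Col-3 gl1 for the 23 members of the fixed gene lists that passed the signal filter, with 2 arrays per line. Points are limma estimates and bars are standard errors; COR15A, at 0.80, lies farthest from 0, and none of the 23 was called over all probe sets by limma.

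The position of called genes was compared because lines can differ in variants linked to a mutation. Each locus was taken at its brightest probe set, which left out AT3G49080, whose called probe set was at -1.26 and whose brightest was at -0.15 and not called (adjusted p = 0.858). Among 9420 tested loci, 40 were called, 8 each on chromosomes 1, 2 and 3, 6 on chromosome 4 and 10 on chromosome 5. The shares of tested loci ran from 0.323% on chromosome 1 to 0.581% on chromosome 2, and no chromosome differed from the rest (Fisher's exact test, two-sided, adjusted p = 1 for each). The 5 Mb window centred on TMM held 289 tested loci. Its called loci were 2, AT1G75180 and ATL8, against 1.23 from an even spread (one-sided permutation test, p = 0.347). No window around GL1 was tested, and a comparison of whole chromosomes cannot show a small cluster.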

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

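The filter at the Bacillus control signal and the comparison of splits were chosen after the results were seen. The 104 calls (41 higher, 63 lower) stayed within 1.5 times, at 84 to 112, with either other pseudocount, scaling to the median, a filter of 3 times the minimum, robust variances or the Bacillus filter. Quantile normalization gave 69 calls (22 higher), no filter 17 (5 higher, 12 lower) and no intensity trend 0 in all, 0 higher and 0 lower. Limma's prior degrees of freedom, 23.6 in the main model, were 13.5, 6.2 and 4.4 there, and the cause was not tested further. They were 1105.4 without tmm-1 replicate 2 and infinite without any other single array. The p-values and calls with an array left out thus rest almost wholly on the prior, and those of the main model rest mostly on it. An adjusted p below 0.1 gave 162 calls, and a 2-fold minimum 55.

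Leaving out an array gave 77 to 662 calls (35 to 345 higher, 42 to 317 lower), with the lone sample assumed to vary like the other line. The 662 came without tmm-1 replicate 1 and 167 without tmm-1 replicate 2, and these shared 99 and 91 of the 104, with 64 shared without control replicate 1 and 78 without control replicate 2. Median list shifts were -0.35 to -0.06 for photosynthesis, 0.08 to 0.31 for abscisic acid and cold, 0.01 to 0.21 for stomatal lineage and 0.15 to 0.42 for trichome. The log2 changes of the genes that turned sign, none of them called, were -0.01 to 0.21 for BRXL2, -0.04 to 0.35 for AGL16, -0.58 to 0.02 for CHX20, -0.68 to 0.38 for ACR4, -0.82 to 0.42 for TRY, -0.57 to 0.46 for EMS1, -0.39 to 0.19 for RCA, -0.01 to 0.33 for ZAT10, -0.03 to 0.31 for LTI30 and -0.12 to 0.11 for ARR15. SPCH ranged from 0.01 to 0.62, FAMA from -0.36 to -0.06, TCX3 from 0.01 to 0.38, EPFL9 from -0.60 to -0.10, LHCB4.1 from -0.43 to -0.13 and GH3.5 from -0.55 to -0.17. The naming rule took only genes whose signals did not overlap between lines, so leaving out an array or changing the pseudocount could not turn their sign. Of the 20 named called genes, 0 turned sign in any setting that tested them. In limma, 0 of them stayed called with no intensity trend, 6 with no filter, and 15 after quantile normalization.

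With the pool number as a replicate block, limma called 191 (72 higher, 119 lower), which held all 104, and COR15A (adjusted p = 0.0393). The deviations of same-numbered arrays correlated at 0.032 across probe sets, so no shared pool effect was seen over all probe sets together. That correlation cannot exclude such an effect in some genes. Whether same-numbered pools shared a day is unknown. The 4 arrays make 3 splits of 2 against 2, too few for a share under 0.05, and 1 of them, the labelled one, gave 104 calls. The highest of the others was 1 call. In those, any difference between the lines adds to the spread within groups, so their few calls do not show what a grouping with no effect gives. No alternatives were run for TMM and GL1, which are not analysed here. Signal over background limits the dim genes, since 12 of the 41 rises started at or under 21.2 on both control arrays and 4 of the 63 falls ended there on both tmm-1 arrays.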

Other observations

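The gene families and the starvation and clock gene lists below were chosen after the data were seen, and so were the tests of single arrays. Among 37 families formed from gene symbols, with 339 tested probe sets, limma's camera called 0, and 3 had an unadjusted p below 0.05. All 7 tau-class glutathione transferase genes (GSTU) had positive log2 changes, with a median of 0.20 (adjusted p = 0.566, or 0.936 as an adjusted p with an estimated correlation). Of 13 genes with SWEET symbols, mostly sugar transporters, 10 were positive, with a median of 0.33 (adjusted p = 0.566). SWEET10 had signals of 145 and 111 in tmm-1 and 106 and 81.7 in the control. Of 11 genes with GH symbols, mostly endoglucanases, 9 were positive, with a median of 0.20 (adjusted p = 0.566).

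Several named genes called lower in tmm-1, among them AKINBETA1, MCCA and ATL8, are known to be induced when plants run short of sugar, while MCCB, IVD and LKR, amino acid breakdown genes looked at with them, were at -0.50, -0.06 and 0.09 and were not called. The single-locus genes called lower without tmm-1 replicate 2 held most of the 27 called falls, with AKINBETA1, MCCA and ATL8 among them. In these genes the left-out array deviated from the control mean by a median of 0.71 of the replicate 1 deviation. The 95% bootstrap interval over genes was 0.61 to 0.87, against 0.30 in a simulation with no effect. These genes were thus mostly lower on both tmm-1 arrays. The interval treats genes as independent and rests on 1 left-out array, so it does not measure the spread between arrays. Over the wider set called lower without replicate 1 the ratio of the left-out array was 0.34 (0.23 to 0.44, against 0.26). Many of that set could rest on replicate 2. A difference in sugar status may account for the falls, but 15 other genes linked to starvation, mostly of autophagy and amino acid breakdown, had a median log2 change of -0.12 with 8 of 15 lower, 0 called by limma and the list not called by camera, and of 4 at an unadjusted p below 0.05, ATG8E and ATG8I were lower and ATG8G and ATG1A higher, which left this open. A difference in harvest hour could also contribute, since COR27 fell, and GI, at -0.47, was lower without being called. COR28 was also lower without being called, but its mean signals of 4.28 in tmm-1 and 18.7 in the control were both under 21.2. The morning genes RVE5, RVE6 and CDF5 were at 0.33, 0.37 and -0.09, a median of 0.33. That was short of the rise in all 3 that was predicted before they were looked at. Which way these 3 would move depends on the hours of harvest, which are not known here, so the test cannot decide. Hour and line cannot be told apart, and an effect of the tmm-1 mutation itself stays open as well.

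Variants linked to TMM could place called genes near it, and variants linked to GL1 could do so on chromosome 3. The window centred on TMM held 2 called loci, AT1G75180 and ATL8. The one-sided permutation test gave p = 0.347, with too few called loci to settle it. No window around GL1 was tested. On its chromosome, called CYP71B22 (AT3G26200) and CCL, both lower, and AT3G26960, higher, had locus numbers near that of GL1. The other called loci there had more distant numbers. This closeness was seen after the calls were made, so a link to GL1 stays open.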
